A study of Homo sapiens with 4 samples.

How the data were processed

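RNA from Panc-1+ve cells was labelled with Cy3 and hybridised to 4 NimbleGen expression arrays, 1 sample per array, per the labels' protocols. The deposited values are intensity on a linear scale, summarised per transcript target by RMA, per the submitters' processing notes. RMA in general combines background correction, normalisation between arrays and a summary over the probes of a target; which of these steps and settings were used, and the version, are not given in the sources used here. The deposited intensity of 45031 targets summarised 3 probes each, and 2 targets had fewer. Array medians, quartiles and highest values nearly coincided, as after a normalisation that equalises distributions, so a change in the total amount of RNA could not appear in them, and values near the top, where 71 targets reached 60000 on at least 1 array, are compressed. A value for 5000 random-sequence probes served as the background level. The deposited series table and the deposited file of each array held equal values (largest difference 0). No flag for saturation or absence was used here.

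Targets carry HG18 coordinates, gene names and Entrez identifiers in the array files. Identifiers of 20230 of 23620 genes matched the RefSeq gene table of assembly GRCh38.p14, which was used for current symbols only; 3390 kept the file's name. A gene was represented by its target with the highest mean, since 11861 genes had several. Tested genes were at or above the array median on at least 2 of the 4 arrays.

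The log2 of each deposited intensity was taken, without a pseudocount. Both siALPPL2 arrays were compared with both controls, siGFP and L2K as a single arm, in limma 3.58.1 (R 4.3.3) with lmFit and eBayes with an intensity trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 2 residual degrees of freedom and 7.33 in total after moderation. Its spread includes the siRNA sequence and the kind of control. A rule of size without a test counted genes at least 2-fold apart in all 4 knockdown-control pairs. Comparisons of 1 array with 1 have no test.

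The tests of the comparisons, the alternatives and 34 gene lists were fixed before the data were examined, except camera at an estimated correlation with 1 array left out and the differences of single list members with 1 array left out, which were chosen after seeing the data. The lists covered alkaline phosphatases, cell cycle (G1/S and DNA replication, G2/M and mitosis), p53 targets, pro- and anti-apoptotic genes, epithelial adhesion, mesenchymal genes, invasion proteases, integrins, interferon, NF-kB, the unfolded protein response, heat shock, NRF2 targets, cholesterol, glycolysis and hypoxia, oxidative phosphorylation, ribosomal proteins, TGF-beta, YAP/TEAD and MAPK targets, RNA interference, stem cell and ductal carcinoma markers, GPI anchors, metallothioneins, lysosome and autophagy, housekeeping genes, and markers of leukocytes, fibroblasts, endothelium, acinar and islet cells. The 29 lists with at least 4 tested genes were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and fry beside it. For 1 array against 1, a list's median was placed among the medians of 10000 random lists of the same size drawn from 20 bins of brightness. Random lists ignore correlation between the genes of a list, so a list of correlated genes leaves their range more easily. A place outside the range is a description and not a test. The covariance expected for unchanged arrays that share a control was taken from 100 simulations.

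The rule for named genes was fixed at the same time. The alkaline phosphatases were always named. For the main comparison the rule took the 12 highest and the 12 lowest genes by the smallest of the 4 differences, given as values where they did not pass. It took up to 4 members of each list by the same rank, of which the text gives a selection, and the 8 largest differences each way where 1 array faced 1, of which 1 gene is not reported here. Other members of lists, RYK in the fit without siALPPL2 replicate 2, and genes outside the range of the other 3 arrays were chosen after their values were seen.

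The fit was tested on simulated data, drawn for the 12042 tested genes with the spreads of the main comparison and 50 genes changed at each size. It called 32% of the genes changed 1.5-fold, 74% at 2-fold, 96% at 4-fold and 100% at 8-fold. The simulation gave every array independent errors. Genes of all sizes were changed in the same simulated data and adjusted together, so the large changes eased the threshold for the small ones. The shares therefore do not hold where few genes change, and they do not exclude 2-fold changes among genes that did not pass.

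Alternatives were no filter, a filter at the 0.75 quantile of brightness, the mean of all targets of a gene, every target by itself, the deposited series table, centring on the median, cyclic loess between arrays, eBayes without a trend or robust, a threshold of 0.10, siGFP as the only control, and leaving out each array in turn. An analysis of siRNA seed matches in 3 prime untranslated regions was planned and not run, as transcript sequences were not used here.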

Results

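The arrays profiled Panc-1+ve cells, a culture of the human pancreatic carcinoma line Panc-1 that expresses ALPPL2. ALPPL2 (ALPG by its current symbol) is a placental-like alkaline phosphatase held at the cell surface by a glycosylphosphatidylinositol (GPI) anchor. RNA was taken 48 h after transfection. There were 4 one-colour arrays, 1 from cells given the lipid transfection reagent alone (L2K), 1 from cells given a control siRNA against GFP at 10 nM (siGFP) and 2 from cells given 10 nM of an siRNA against ALPPL2 (siALPPL2). The label of siALPPL2 replicate 1 names siRNA siALPPL2-2. That of siALPPL2 replicate 2 gives no siRNA number, and the protocol lists siALPPL2-3 as the other ALPPL2 siRNA used, so the 2 arrays are taken to hold a different siRNA each. On that reading no treatment was repeated, and p-values measure the spread between these arrays. That spread includes the siRNA sequence and the kind of control, along with any culture or technical differences. Nothing in the labels says whether the arrays came from independent experiments.

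Each array held 45033 transcript targets, with median intensities between 2329.8 and 2482.3 and a level for random-sequence probes between 58.4 and 66.1. The number of arrays limits the precision of every value below. Of 23620 genes, 12042 were bright enough to test.

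The targeted gene came first, as a check of the labels. The ALPPL2 target (HG18 chromosome 2, 232979810 to 232983661, the span of the ALPPL2 transcript in the array's annotation) read 58149 on L2K, 55566 on siGFP, 14417 on siALPPL2 replicate 1 and 37969 on siALPPL2 replicate 2. It was 3.85-fold lower than siGFP on replicate 1 and 1.46-fold lower on replicate 2, and the further ALPPL2 target was 3.73-fold and 1.34-fold lower. With all 4 arrays in limma the log2 difference was -1.28 ± 0.37 (SE, 2 arrays against 2), with an adjusted p of 0.707, the 2 siALPPL2 arrays standing 2.63-fold apart. Against both controls each siALPPL2 array taken alone gave a fall in ALPPL2. For replicate 1, without replicate 2, the log2 difference was -1.98 ± 0.11 (limma adjusted p = 1.51e-04), and for replicate 2, without replicate 1, it was -0.58 ± 0.06 (limma adjusted p = 0.0478). These fits assume that the lone siALPPL2 array varies like the controls; over all alternatives the adjusted p of ALPPL2 ranged from 1.51e-04 to 0.828. Both controls lay above 99.0% of all targets on their array, near the highest values of 62510.1 to 63343.3, so the folds may be understated.

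The relatives of ALPPL2 did not all behave alike. ALPP, the placental alkaline phosphatase (chromosome 2, 232951703 to 232955836), read 3599 on L2K, 53269 on siGFP, 8714 on siALPPL2 replicate 1 and 21808 on siALPPL2 replicate 2. Its direction in the knockdown arrays therefore depended on the control, 6.11-fold and 2.44-fold below siGFP but 2.42-fold and 6.06-fold above L2K. ALPI, the intestinal form, read 1483, 1539, 930.3 and 1058.5 in the same order, below the brightness filter. Like ALPPL2 it was below both controls, 1.65-fold and 1.45-fold below siGFP on siALPPL2 replicates 1 and 2, and 1.595-fold and 1.40-fold below L2K. The 2 targets of ALPL, the tissue-nonspecific form, read between 447.6 and 1177, also below the filter. ALPPL2, ALPP and ALPI are closely similar in sequence, which leaves the share of each target's signal that belongs to its own transcript uncertain. Of the 2 alkaline phosphatases tested, ALPPL2 passed limma adjusted over the list alone, and 0 passed over all genes, with 1 at an unadjusted p under 0.05.

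**Figure D1:**
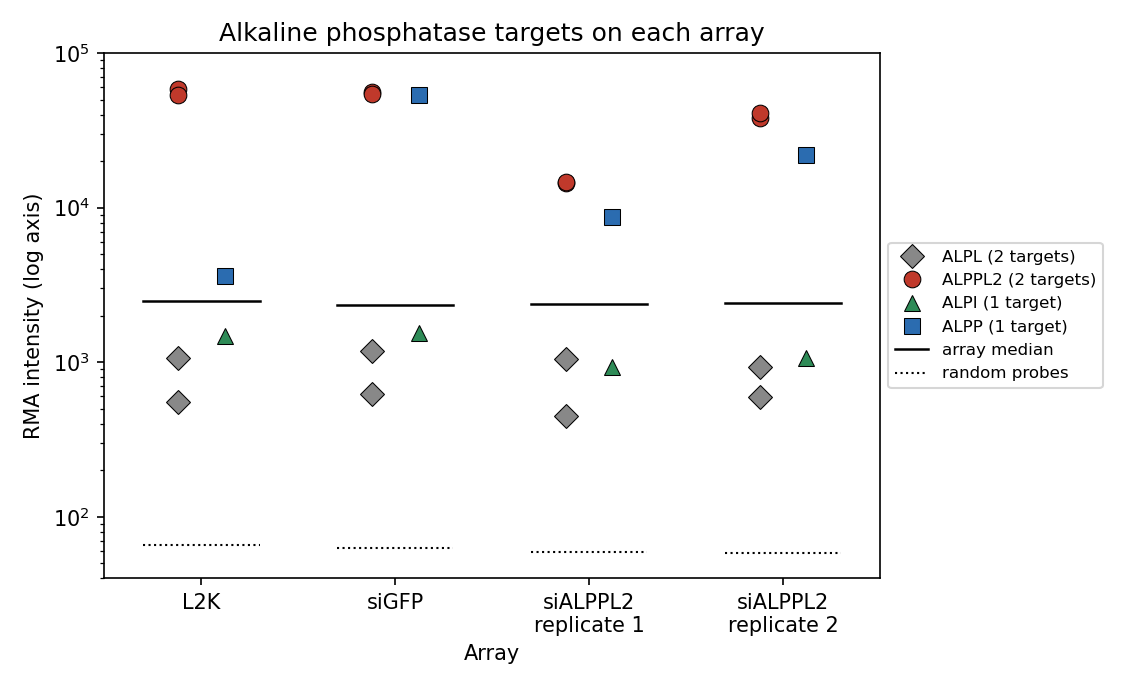
RMA intensity (log axis) of each alkaline phosphatase target on the 4 arrays, 1 point per target, with the array median as a line and the random-probe level as a dotted line. Both ALPPL2 targets are lowest on siALPPL2 replicate 1 (14417 and 14662), and ALPP runs from 3599 on L2K to 53269 on siGFP.

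The main comparison asked which transcripts differed when ALPPL2 was targeted, with both siALPPL2 arrays set against both controls. Among the genes furthest above both controls were C8orf82, a little-studied gene, at 7769 and 7758 against 3478 on L2K and 3799.8 on siGFP, METRN, a secreted neurotrophic factor, at 28543 and 33016 against 15768 and 14004, and LIMK1, a kinase of cofilin, at 18030 and 15805 against 8637 and 9449. Their log2 differences were 1.09 ± 0.16, 1.05 ± 0.15 and 0.90 ± 0.15 (SE, 2 against 2). Furthest below were CREBL2, a leucine zipper protein, at 5271 and 5267 against 10647 and 10820.5, NEMP1, a nuclear envelope protein, at 10936 and 9744 against 18873 and 19672, and EIF4EBP2, a repressor of cap-dependent translation, at 17862 and 16939.9 against 29159 and 30984. Their log2 differences were -1.03 ± 0.14, -0.90 ± 0.15 and -0.79 ± 0.13.

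None of these passed the test. With limma 0 of 12042 genes had an adjusted p under 0.05, the lowest being 0.683, and 774 genes (6.43%) had an unadjusted p under 0.05, 417 of them higher and 357 lower. The other 2 ways of splitting the 4 arrays into pairs gave 592 and 259 such genes. C8orf82 and CREBL2 were the 2 genes at least 2-fold apart in all 4 knockdown-control pairs, while the other splits gave 2 and 0 genes, and after cyclic loess this count was 0. With 1 array left out 2 pairs remain, an easier rule, and the genes at least 2-fold apart in both pairs numbered 10 without siALPPL2 replicate 1, 7 without siALPPL2 replicate 2, 7 without siGFP and 81 without L2K. At 1.5-fold the real split gave 7 higher and 4 lower genes, and the other splits gave 17 and 4 in all.

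The remaining genes named by the same rank are given as values. Above both controls stood CCN5, a matricellular protein (log2 difference 0.89), LONP1, the mitochondrial matrix protease (0.87), the calpain CAPN5 (0.76), FOXC2, a forkhead transcription factor (0.72), the potassium channel KCNK15 (0.77), FAM83H (0.80), the neuropeptide Y receptor NPY4R (0.82), PGLS of the pentose phosphate pathway (0.62) and ZNF775 (0.66). Below both stood IL6R, the interleukin-6 receptor (-0.95), LONRF3 (-0.78), XRCC2, a homologous recombination protein (-0.65), KIAA1618 (-0.77), the zinc finger gene ZNF548 (-1.12), FOXA1, a pioneer transcription factor (-0.89), the centromere protein CENPN (-0.64) and the histone H4 gene H4C2 (-0.53), whose family has near-identical copies. For ZNF548, IL6R and FOXA1 the controls themselves were apart, at 3699, 12389 and 6573 on L2K against 6980.3, 18831 and 10191 on siGFP, and without siGFP ZNF548 was at -0.66 and FOXA1 at -0.58. Of the 24 named genes, 14 had a further target above the filter, and all 18 such targets went in the direction of the chosen target. For C8orf82, KCNK15 and NPY4R the further targets passed the filter on the siALPPL2 arrays alone. That of CREBL2 passed it on the controls alone. For these genes the filter itself fixed the direction. Targets of a gene also share the RNA of each array, so they are not independent measurements of a difference.

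**Figure D2:**
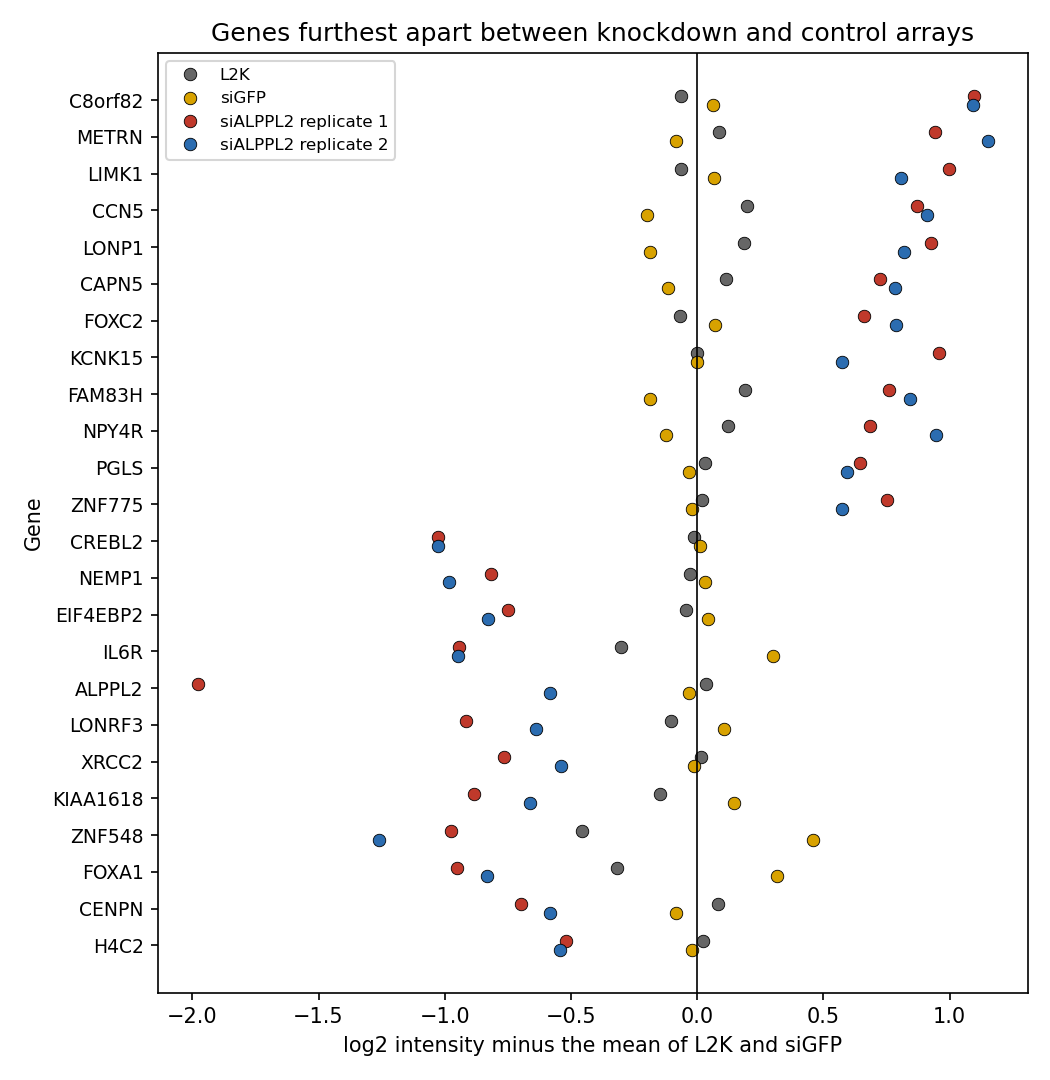
For the 24 named genes, log2 intensity on each array minus the mean of L2K and siGFP, 1 point per array. C8orf82 and CREBL2 are the genes with a gap of at least 2-fold in every pair, and ALPPL2 is the gene whose siALPPL2 arrays lie furthest apart, at -1.98 and -0.58.

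Without siALPPL2 replicate 2, 2 genes fell with siALPPL2 replicate 1 against both controls in limma. They were ALPPL2 and RYK, a receptor of Wnt ligands, at 18868 against 42985 on L2K and 46674 on siGFP (log2 difference -1.25 ± 0.13, limma adjusted p = 0.0184). RYK read 46526 on siALPPL2 replicate 2, and its further target gave the same picture, at 1.39 log2 below the mean of the other 3 arrays. Without siALPPL2 replicate 1, ALPPL2 was the 1 gene that passed.

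Cell cycle genes were the groups that stood out. The G2/M and mitosis list (35 genes tested) had a median log2 difference of -0.17 and fell in limma's camera test (adjusted p = 1.12e-07 over 29 lists), and the G1/S and DNA replication list (36 genes) had a median of -0.14 and fell as well (adjusted p = 6.52e-04). With an estimated correlation between genes both were lost, each at adjusted p = 0.922 with an estimated correlation, and limma's fry test gave 0.932 for both. In mitosis 17 genes (48.6%) were below both controls on both siALPPL2 arrays and 0 above, against 2742 (22.8%) below and 2053 above among the 12042 tested genes and 16.7% each way for independent arrays. Most mitosis and replication genes were lowest on siALPPL2 replicate 1. A lone low array by itself raises the share below and lowers the share above, so these shares do not measure agreement between the siRNAs. In mitosis the genes furthest below follow. CDC25C (log2 difference -0.50 ± 0.15), NUF2 (-0.53 ± 0.17), TTK (-0.49 ± 0.18) and KIF2C (-0.27 ± 0.08) were the furthest. In replication 15 (41.7%) were below and 2 above, led by CDC6 (-0.52 ± 0.17), POLA1 (-0.52 ± 0.19), CCNE2 (-0.42 ± 0.18) and MCM10 (-0.40 ± 0.19). In both lists 0 genes passed limma over all genes and 0 adjusted over the list alone, with 9 mitosis and 2 replication genes at an unadjusted p under 0.05. Without siALPPL2 replicate 1 TTK was at -0.27, CDC6 at -0.34, CCNE2 at -0.24 and MCM10 at -0.14, and without siGFP POLA1 was at -0.29.

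The shift lay on siALPPL2 replicate 1. There 33 of the 35 mitosis genes and 31 of the 36 replication genes had their lowest value of the 4 arrays, among them CDK1 at 18342 against 28392 to 29726 on the others, and CENPA at 14548 against 21717 to 25000.0. The 4 fibroblast and stellate cell markers above the filter were also outside the range of matched random lists on that array, with a median log2 difference of -0.37 from the other 3 arrays and 3 of 4 lower. The MAPK (-0.16), interferon (-0.16), mesenchymal (-0.11), stem cell (-0.10) and NF-kB (-0.05) lists lay below that range as well. Oxidative phosphorylation (0.05) and ribosomal proteins (0.03) lay above it, so the shift of that array was not confined to cell cycle genes. Relative to each gene's mean over the arrays, the mitosis median was 0.14 on L2K, 0.06 on siGFP, -0.27 on siALPPL2 replicate 1 and 0.02 on siALPPL2 replicate 2. Without siALPPL2 replicate 1, the mitosis median was -0.02 (limma camera adjusted p = 0.411) and that of replication -0.01 (0.971), while without siALPPL2 replicate 2 the medians were -0.33 for both. Over all alternatives the limma adjusted p ranged from 2.74e-21 to 0.992 for mitosis and from 1.65e-14 to 0.992 for replication. The count of lists past camera was 0 without siALPPL2 replicate 1, 6 without siALPPL2 replicate 2, 6 without siGFP and 5 without L2K, and with an estimated correlation it was 0 in each. Mitosis and replication also passed camera in both other splits of the arrays, which called 12 and 8 lists against 2 in the real split, and siALPPL2 replicate 1 lies on 1 side of every split.

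**Figure D3:**
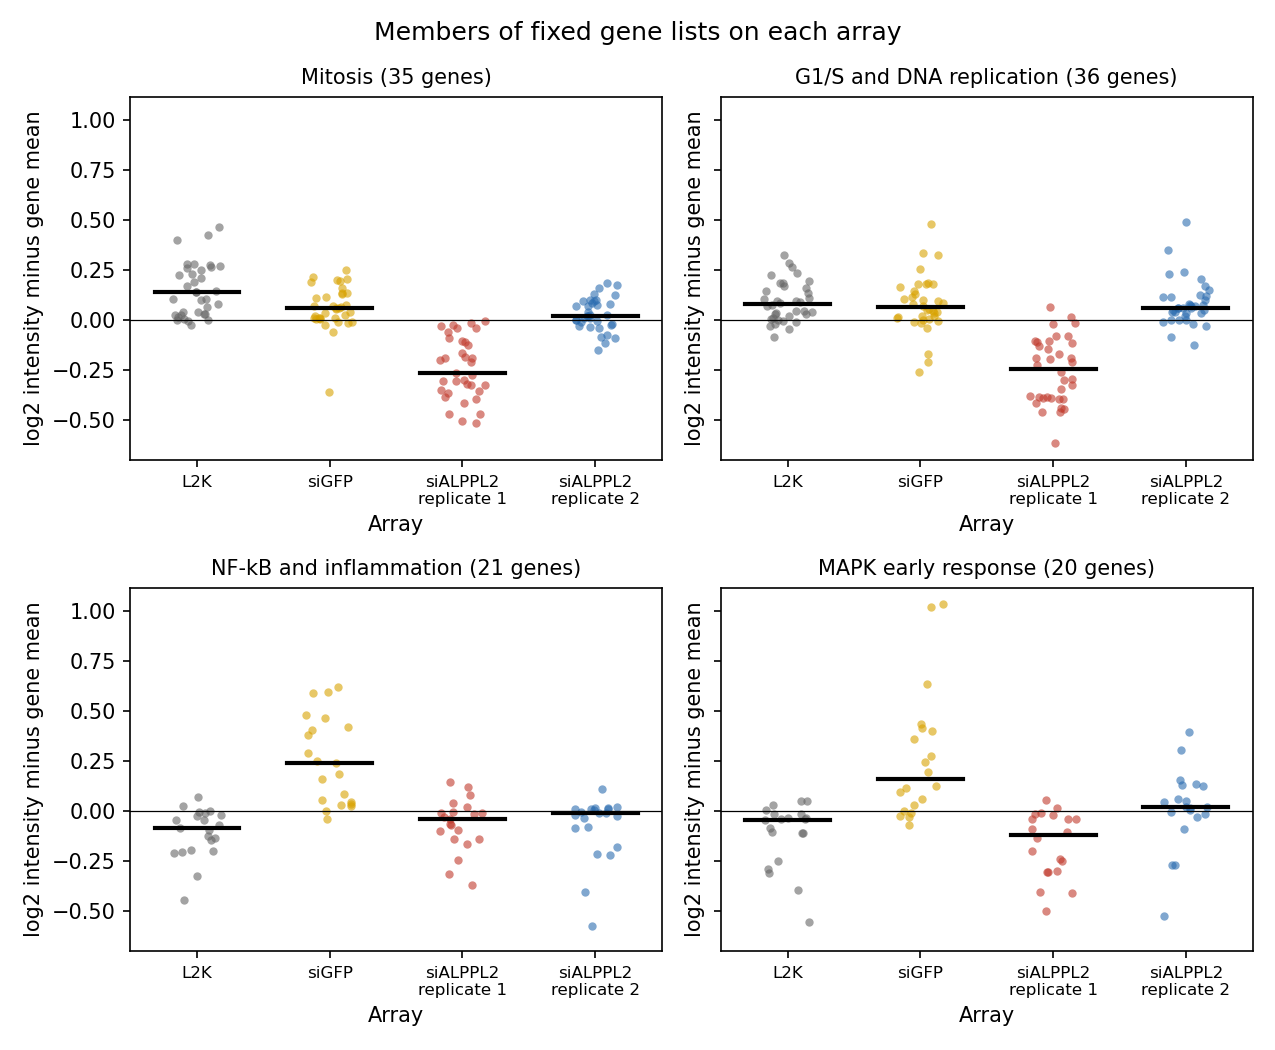
Members of 4 gene lists on each array, as log2 intensity minus the gene's mean over the 4 arrays, 1 point per gene, with the list's median as a bar. The mitosis and replication medians are lowest on siALPPL2 replicate 1 (-0.27 and -0.24), and those of the NF-kB and MAPK lists are highest on siGFP (0.24 and 0.16).

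No other list passed camera in the comparison of both siALPPL2 arrays with both controls. Of the 29 lists 5 were under 0.05 before adjustment, mitosis, replication, NF-kB and inflammatory mediators (median log2 difference -0.10, limma camera adjusted p = 0.227), the unfolded protein response and ATF4 list (-0.08, limma camera adjusted p = 0.274) and ribosomal proteins (0.02, limma camera adjusted p = 0.274). The interferon-stimulated genes had a median of -0.03, with ISG15 at 0.45 ± 0.17 and IFIH1 at -0.56 ± 0.22. Among epithelial adhesion genes (median -0.02) EPCAM was at -0.57 ± 0.19. The mesenchymal list had a median of 0.03 with 1 of 14 genes, FOXC2, past limma's threshold adjusted over the list alone and 0 over all genes, where 2 had an unadjusted p under 0.05. Medians were -0.06 for p53 targets, -0.05 for pro-apoptotic and -0.01 for anti-apoptotic genes. They were -0.01 for invasion proteases, -0.02 for integrins and focal adhesion, -0.04 for heat shock genes and 0.02 for NRF2 targets. Cholesterol synthesis stood at 0.02 with TM7SF2 at 0.83 ± 0.29, glycolysis and hypoxia at -0.01 with PFKL at 0.44 ± 0.13, and oxidative phosphorylation at 0.02 with NDUFA2 at 0.24 ± 0.06. TGF-beta targets were at 0.05, YAP/TEAD targets at -0.07, with FJX1 at 0.75 ± 0.22, and MAPK and immediate-early genes at -0.06, with DUSP6 at -0.93 ± 0.33. RNA interference genes were at -0.04, with AGO3 at -0.52 ± 0.15, and stem cell markers at -0.02, with LIN28B at -0.81 ± 0.29. Ductal carcinoma markers were at 0.00, metallothioneins at -0.05, lysosome and autophagy genes at 0.03 and housekeeping genes at -0.01. The list of GPI anchor synthesis and GPI-anchored proteins, the class to which ALPPL2 belongs, was at 0.02, with PIGA at -0.50 ± 0.15 and PIGQ at 0.54 ± 0.20. Some of these genes differed between the controls themselves, DUSP6 at 6293 on L2K and 13846 on siGFP, LIN28B at 4749 and 8517, and IFIH1 at 8294 and 13149.6. Without siGFP the log2 differences were -0.36 for DUSP6, -0.39 for LIN28B, -0.23 for IFIH1, 0.44 for TM7SF2, 0.49 for FJX1 and 0.28 for PIGQ, and without L2K they were -1.50, -1.23, -0.90, 1.22, 1.01 and 0.80. Without siALPPL2 replicate 1 TM7SF2 was at 0.55. Several of the medians turned with the control. Without siGFP the medians were 0.02 for NF-kB, 0.06 for interferon-stimulated genes, 0.01 for MAPK and immediate-early genes, 0.02 for NRF2 targets and 0.09 for TGF-beta targets. Without L2K they were -0.26, -0.14, -0.17, -0.03 and -0.04. The GPI median also turned, at -0.07 and -0.08 on siALPPL2 replicates 1 and 2 against L2K alone, and 0.11 and 0.08 against siGFP alone. At camera's preset correlation the lists past limma's threshold were interferon, NRF2 and TGF-beta (higher) and ribosomal proteins (higher, 0.03) without siGFP, and NF-kB, interferon and MAPK (lower) without L2K. Without siALPPL2 replicate 2, MAPK (-0.14) passed as lower, and oxidative phosphorylation (0.03), ribosomal proteins (0.03) and lysosome and autophagy genes (0.06) passed as higher. With an estimated correlation all of these calls were lost, at an adjusted p = 0.908 without siGFP, 0.865 without L2K and 0.960 without siALPPL2 replicate 2.

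For glycolysis and hypoxia, invasion proteases and integrins the median was negative and camera's direction up, and for ductal carcinoma markers the median was positive and camera's direction down. Outside the alkaline phosphatase and mesenchymal lists, 0 genes passed limma adjusted over the list alone.

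Markers of other cell types differed in signal. Leukocyte (18 genes on the array), endothelial (10) and acinar markers (15) had 0 genes above the filter, and islet markers had 1 of 15, PDX1, at -0.19 ± 0.15 and at -0.12 without siGFP. Of 15 fibroblast and stellate cell markers 4 were above it, COL1A1, COL3A1, THY1 and FBLN1, with a median of -0.10 (limma camera adjusted p = 0.808). COL3A1 was at -0.23 ± 0.08. FBLN1 read 49066 to 55018 and COL3A1 32015 to 39049.8 over the 4 arrays, and the mesenchymal list also holds COL1A1, COL3A1 and THY1. On siALPPL2 replicate 1 the median of the 4 was -0.28 against L2K and -0.38 against siGFP, and on siALPPL2 replicate 2 it was 0.35 against L2K and -0.03 against siGFP.

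The control siRNA was set against the reagent alone, with 1 array each and therefore no test. On siGFP 133 genes were at least 2-fold from L2K, 35 higher and 98 lower, and after cyclic loess 50 higher and 73 lower. Furthest above L2K was ALPP (14.8-fold), followed by BCAP29 (4.35-fold), ANGPTL4, an inhibitor of lipoprotein lipase (2.83-fold), VSIR (2.63-fold), SNCG (2.59-fold), CSPG5 (2.51-fold) and the neurotrophin receptor NGFR (2.51-fold). The BCAP29 difference was not borne out by that gene's further target, which was 0.44 log2 higher on L2K than on the other 3 arrays. Furthest below were HNRNPM, a splicing factor, at 8514 against 33938.0 (3.99-fold), PHF7 (3.73-fold), ANKRD42 (3.63-fold), CFAP45 (3.26-fold), PCYOX1L (3.23-fold), NANOS1 (3.23-fold), TTLL1 (2.98-fold) and NSF, an ATPase of vesicle fusion (2.89-fold).

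Inflammatory and signalling genes were higher on siGFP than on L2K. Of 21 NF-kB genes 20 were higher, with a median log2 difference of 0.27, among them RELB (2.09-fold), NFKBIE (1.74-fold), CXCL8 (1.73-fold) and NFKB2 (1.63-fold). Of 25 interferon-stimulated genes 22 were higher (median 0.30), with XAF1 and IRF1 at 0.81 and 0.80. MAPK and immediate-early genes had 16 of 20 higher (median 0.17), with HBEGF 2.41-fold and DUSP6 2.20-fold. Of 29 tested lists, 11 lay above and 1 below the central range of 10000 random lists matched on brightness. The others above were NRF2 targets (0.20), TGF-beta targets (0.11), invasion proteases (0.11), pro-apoptotic genes (0.10), mesenchymal genes (0.08), YAP/TEAD targets (0.07), epithelial adhesion (0.05) and ribosomal proteins (0.02). The list below was the GPI list (-0.16), with 19 of 29 genes lower, among them PIGW at -0.93 and PIGM at -0.82, and after cyclic loess 10 lists lay above and 0 below. The estimated correlation between genes was 0.64 in the NF-kB list, 0.42 in MAPK and 0.38 in interferon, which random lists ignore. These counts therefore do not show that pathways shifted.

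The siALPPL2 arrays were also set against each other, again with 1 array each. At least 2-fold apart were 40 genes, 14 higher and 26 lower on replicate 1. Higher there were ADAMTS1, a secreted metalloprotease of the ADAMTS family (3.20-fold), IL1R1 (2.75-fold), EPB41L5 (2.40-fold), MT1F (2.28-fold), RAB29 (2.23-fold), RPS17P12 (2.20-fold), TAF11 (2.17-fold) and FBXL16 (2.13-fold). Lower there were ALPPL2 (2.63-fold), COX6B2 (2.58-fold), RASL10B (2.51-fold), ALPP (a log2 difference of -1.32), CACNG7 (2.47-fold), RYK (2.47-fold), INAVA (2.39-fold) and ARHGEF40 (2.38-fold). The IL1R1 difference rested on the chosen target, since on replicate 2 the gene's 2 further targets deviated from the other arrays by -0.12 and -0.25 log2, against -1.68 for the chosen one.

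Between these arrays 10 lists lay below and 3 above the range of random lists, which again ignores correlation within a list. On replicate 1 replication (median log2 difference -0.33, 34 of 36 genes lower) and mitosis (-0.27, 34 of 35 lower) were lower, as were TGF-beta targets (-0.17), MAPK and immediate-early genes (-0.16), metallothioneins (-0.15), mesenchymal genes (-0.12), interferon-stimulated genes (-0.11), cholesterol synthesis (-0.10), YAP/TEAD targets (-0.07) and the 4 fibroblast markers (-0.46). Oxidative phosphorylation (0.06), lysosome and autophagy genes (0.06) and ribosomal proteins (0.02) were higher.

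The last comparison asked whether the siRNAs against ALPPL2 moved the same genes. Across the 12042 genes, which are not independent replicates, the responses correlated at r = 0.742 with siGFP as the shared control and at 0.534 with L2K, against 0.499 simulated for unchanged arrays that share a control. The covariances were 0.0771 and 0.0306 against 0.0366 simulated, differences of 0.0405 and -0.00598. The simulation gave every array the same spread, but siGFP stood further from the others. Log2 differences had an SD of 0.30 to 0.33 in pairs with siGFP and 0.23 to 0.25 in the other pairs. A shared control that deviates more raises the covariance by itself, so the excess with siGFP cannot be read as a common response. With a different control for each siRNA, so that no array was shared, the covariances were 0.0135 (r = 0.187) and 0.00388 (r = 0.0471), against 1.31e-04 simulated. Their mean was 0.00868, against 0.00286 and -0.0115 for the other 2 splits of the arrays. The means of the 3 splits cancel out by construction, so the other 2 are not an independent reference. No test is possible on 3 splits.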

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

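Among the alternatives in this paragraph, camera with an estimated correlation and 1 array left out was chosen after seeing the data. No paired analysis was possible because the labels give the control arrays no replicate numbers to pair with. The seed-match analysis was not run. The count of genes past limma's threshold stayed at 0 under every filter, choice of target, scaling and variance model tried, with siGFP as the only control and at a threshold of 0.10; leaving out 1 array each it ranged from 0 to 2. Genes at least 2-fold apart in all 4 pairs, 2 as reported, numbered 17 with no filter, where dim genes enter, 5 with every target by itself, 1 with the mean of targets, 1 after median centring, 0 with a filter at the 0.75 quantile of brightness, 0 after cyclic loess, and 11 at 1.5-fold. Where 2 pairs remain, an easier rule, the count was 81 with siGFP as the only control and from 7 to 81 with 1 array left out. C8orf82 and CREBL2 have smallest gaps of 2.04-fold and 2.02-fold, so small shifts move them across 2-fold; other causes were not tested. The ALPPL2 difference was negative throughout and passed the threshold with either siALPPL2 array left out, with a range over single arrays left out of -1.98 to -0.58, where the spread between the siALPPL2 arrays no longer enters. The other 23 named genes kept direction and side of the threshold in all 184 refits. They were chosen for the same sign in all 4 pairs, so leaving out an array or using only siGFP as control could not reverse them. The deposited series table, which held equal values, could not do so either. The count of lists past camera, 2 as reported, was 0 with an estimated correlation, 0 with fry, 5 with siGFP as the only control, 0 to 6 with 1 array left out and 0 in each of those with an estimated correlation. Mitosis (median -0.17) and replication (median -0.14) passed with no filter, the mean of targets and cyclic loess, and not with an estimated correlation (-0.17 and -0.14) or fry (-0.17 and -0.14), whose medians are the same; with 1 array left out the medians ranged from -0.33 to -0.0209 and from -0.33 to -0.0127, the calls ending without siALPPL2 replicate 1. With an estimated correlation as well neither passed, at the same medians (-0.25 and -0.18 without siGFP, -0.12 and -0.15 without L2K). With no filter the genes at least 2-fold apart went from 133 to 748 between siGFP and L2K and from 40 to 188 between the siALPPL2 arrays, as dim genes enter. Over all alternatives the lists outside the random range numbered 8 to 12 and 11 to 13, and the mean crossed covariance was 0.00688 to 0.0112. Dim targets near the random-probe level of 58.4 to 66.1 and bright ones near the ceiling limit what folds can show.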

Other observations

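The tests of the cell cycle and ALPP patterns were chosen after the result was seen, and those of the siGFP pattern before it. Genes that a lone array held outside the range of the other 3 were counted as a description. At least 2-fold outside were 5 genes on L2K, 55 on siGFP (48 lower and 7 higher), 3 on siALPPL2 replicate 1 and 5 on siALPPL2 replicate 2. On siGFP the higher genes included NGFR (2.43-fold above the nearest array), HBEGF, a ligand of the EGF receptor (2.41-fold), the kinase WNK4 (2.31-fold), DUSP6, a phosphatase of ERK (2.20-fold), CD83 (2.10-fold) and ANGPTL4 (2.08-fold). The lower ones included HNRNPM (3.99-fold), PCYOX1L (3.04-fold), TTLL1 (2.80-fold), NGEF (2.75-fold) and NANOS1 (2.69-fold). On siALPPL2 replicate 1 the lower genes were ALPPL2, RYK and DCP2, the mRNA decapping enzyme, whose further target was 0.97 log2 below the other arrays. On siALPPL2 replicate 2 RAB29, a GTPase of the lysosome and Golgi, and SUCO were low on both of their targets, at -1.18 and -1.28 log2 from the other arrays for RAB29 and -1.17 and -1.08 for SUCO.

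Against the mean of the controls, siALPPL2 replicate 2 was lower in the unfolded protein response and ATF4 list, with a median of -0.13 log2 and 22 of 29 genes lower, and it was at -0.11 against L2K alone and -0.11 against siGFP alone, each outside the range of 10000 matched random lists. TRIB3, a pseudokinase induced by ATF4, stood at 1480.3 against 2899.5 to 3081.9 on the other arrays, SEL1L, of endoplasmic reticulum degradation, at -0.49 and the transcription factor XBP1 at -0.45. Some lists outside that range against the mean of the controls were outside it against 1 control and not the other. On replicate 2 the p53 target list was at -0.25 against siGFP and -0.00598 against L2K, mesenchymal genes at 0.22 against L2K and 0.04 against siGFP, and TGF-beta targets at 0.12 against L2K and 0.00651 against siGFP. On siALPPL2 replicate 1 MAPK and immediate-early genes were at -0.23 against siGFP and -0.05 against L2K, and lysosome and autophagy genes at 0.10 against siGFP and 0.00149 against L2K. In limma's camera with each siALPPL2 array alone, assumed to vary like the controls, MAPK (adjusted p = 0.00582) and lysosome and autophagy genes (0.0393) passed on replicate 1 at the preset correlation, each at an adjusted p = 0.960 with an estimated correlation. On replicate 2 the unfolded protein response list was at an adjusted p = 0.0918, p53 targets at 0.774, mesenchymal genes at 0.222 and TGF-beta targets at 0.411.

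The first pattern is the low cell cycle lists on siALPPL2 replicate 1, where the 4 fibroblast markers were also low (median -0.37 log2 relative to the other 3 arrays). The MAPK, interferon, mesenchymal, stem cell and NF-kB lists were low there too, and oxidative phosphorylation and ribosomal proteins were high. Brightness of the genes as the cause is argued against by the mitosis median of -0.354 log2 relative to the other 3 arrays, below all 10000 matched random lists. An odd siGFP control is argued against by the median of -0.444 relative to L2K alone, also below all of them. On siALPPL2 replicate 2 the median was -0.0209 relative to the controls, within the central range of matched random lists (-0.0523 to 0.0472). That array thus showed no shift of the mitosis list beyond random lists, but its loss of ALPPL2 was also smaller. A response to ALPPL2 loss shared by both siRNAs is therefore neither shown nor excluded. The lists may follow the deeper loss of ALPPL2 on replicate 1, an unintended target of that siRNA such as RYK, or the state of that culture, which cannot be told apart with 1 array per siRNA.

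The second pattern is the siGFP array itself. An intensity trend between arrays is argued against by the count of 51 genes outside after cyclic loess, against at most 5 on another array. Noise in dim genes as the whole cause is argued against by the 12 such genes at or above the 0.75 quantile of brightness, against at most 2 on another array. That filter kept 6486 of the 12042 tested genes but only 12 of the 55 outside on siGFP. For the dimmer genes among the 55 this count does not address noise. Faults of particular targets are argued against by the further targets of 27 genes, which deviated in the same direction in 27 of 27 genes with a median of 1.25 log2. The genes outside on siGFP were selected for differing from both siALPPL2 arrays, so they cannot test a response to siRNA in general. Among all tested genes, 19 on siALPPL2 replicate 1 and 24 on siALPPL2 replicate 2 were at least 2-fold from L2K, against 133 on siGFP. Both siALPPL2 arrays also received siRNA at 10 nM. These counts argue against a response to siRNA in general as the whole cause of the 133. A sequence-specific effect of the GFP siRNA and handling of that culture remain as hypotheses, and no test here separates them.

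The third pattern is ALPP, low on L2K and high on siGFP, with ALPPL2 near the ceiling on both arrays. Cross-hybridisation of ALPPL2 transcript to the ALPP target as the whole cause is argued against by the siALPPL2 arrays, where ALPP was at 1.28 and 2.60 log2 relative to L2K and ALPPL2 at -2.01 and -0.61, a gap of at least 3.21 log2 that a ceiling on L2K can only narrow. A share of the ALPP signal from ALPPL2 stays open, since on the other 3 arrays both were highest on siGFP and lowest on siALPPL2 replicate 1. A fault of the ALPP target on 1 array cannot be told apart from a difference in transcript, because the array held 0 further ALPP targets. ALPP was above L2K on all 3 arrays with an siRNA, and a further measurement of ALPP in these cultures could separate the possibilities.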
